A study of Homo sapiens with 87 samples.

How the data were processed

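Each array compared RNA of a hepatocellular carcinoma in channel 1 with RNA of non-cancerous liver in channel 2, per the labels. The labels name no dyes, no dye swap and no ratio direction, and do not state whether the liver RNA was pooled or taken from the same person. The deposited value table gives 1 value per probe and array. Its unit is log10 of a ratio: when base 10 is undone, 100% of the deposited values are whole multiples of 0.001 (within 1e-05 plus a relative 2e-06), against 2.25% for base 2. The authors' background correction, normalization and filtering are not given in the sources used here. Array medians of the deposited values ran from -0.14 to 0.07 on the log2 scale, 3.58% of cells were empty, and ratios ran from 0.002 to 411.1. Channel intensities were not used here, so signal over background is unknown.

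Values were converted to log2 and centred on each array's median. Of 9128 probes, 6318 had 1 gene symbol in the annotation used, 106 had several and 2704 had none there. The 106 and 2704 stayed as unnamed features. Entrez gene IDs were matched to RefSeq genes of GRCh38.p14 for names, where 3 probes had no match and 0 symbols changed. The same annotation marked Y-linked genes and gave the gene order for the windows of neighbouring genes. Probes of a gene were averaged, which left 8634 features, of which 462 genes had more than 1 probe. Among 448 such genes tested in P, 33 had probes past the threshold in opposite directions. No coordinates are given, because the series names no genome build.

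The number in a sample's name was taken as the case, and the code after it as the group. In 26 instances a case had a pair of arrays in a group; these correlated at 0.64 to 0.94 (median 0.89) and were averaged. Nothing in the labels says that cases are different persons, and p-values measure the spread between cases. The lowest correlation between any arrays was -0.15. The T array and 7 arrays without a code entered no comparison. All 20 same-case correlations of P and M deviations were above 0.1 (lowest 0.20), so the case numbers, which come from the labels, were taken to pair P and M.

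A feature was tested if it had a value in at least 70% of the cases of each group. Groups were tested against 0 or against each other with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Against 0, the liver RNA acts as 1 control without its own spread. Of 37 gene lists fixed before the data were examined, 36 had at least 4 measured genes. They were tested with cameraPR at a preset correlation of 0.01 and, as a second value, with the correlation estimated from the residuals. List scores per case, the mean log2 ratio over a list's genes, were tested with 100000 permutations, an alternative added after the data were seen. Genes were named by a rule set beforehand. It took the 12 highest and 12 lowest ratios in P among genes past the threshold with 1 sign in at least 90% of P cases, up to 4 members of a list by smallest p, the 5 smallest p for M against P, up to 12 in each direction past the threshold for the comparisons with PN, and SPP1, AFP, GPC3, MMP9, RHOC and ALB. XIST and Y-linked genes were left out of all gene tables. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

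The code was tested on simulated data with the real spreads and gaps, a shifted cell cycle list and 100 further genes changed at each of 2 sizes (99 at each for M against P with the case as a block). For P against PN (8478 features) it recovered 46% of changes of 0.5 and 90% of changes of 1 on the log2 scale. For P against liver (8521 features) it recovered 79% and 98%, and for M against P with the case as a block (8414 features) 87.9% and 100%. In the P against PN simulation 9.68% of calls were unchanged genes. Noise was drawn independently for each gene, while genes of many lists correlated in the real data, so these shares may not carry over. Alternatives fixed beforehand were no centring, quantile normalization, other presence filters, single probes, all arrays with the case as a random block, only 1 array per case, robust eBayes, array weights, an unadjusted p under 0.001, leaving out each case, the case as a block and the database number as a covariate. Scaling arrays to one median absolute deviation and leaving out 6 arrays with fewer than 8500 probes were added later. Of these arrays 2 were P, 3 were M and 0 were PN, and the remaining array had no group and entered no comparison.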

Results

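Gene expression in human hepatocellular carcinoma was measured on 87 arrays with 2 colours, each of which hybridised tumour RNA together with RNA of non-cancerous liver. The sample names give a case number and a letter code, P, M, PN or T, whose meaning the labels do not spell out. Of the arrays, 30 were P samples of 21 cases, 29 were M samples of 20 cases, 20 were PN samples of 12 cases and 1 was a T sample. The 7 remaining arrays had no letter code and entered no comparison. All 20 M cases also had a P sample, and no PN case had a P or M sample. Between 7799 and 9114 of 9128 probes had a value on an array, and the number of cases limits the precision. Values are log2 ratios, and a positive value likely means higher in tumour than in non-cancerous liver. The basis for that direction is that the median of the cell cycle genes lay above those of the hepatocyte plasma proteins and of the cytochromes P450 in 73 of the 80 arrays with a group. The directions of these 3 gene groups against liver thus fixed the sign and are not independent findings. Each case counted once, and values are given as mean ± SD over cases.

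The first question was which genes differ between hepatocellular carcinoma and non-cancerous liver. In P, GPC3, a cell surface proteoglycan of fetal liver, stood at 2.78 ± 1.56 (SD, n = 21), which is 6.89-fold higher in tumour, and was above 0 in 19 of 21 cases. UBD, a ubiquitin-like modifier, was 5.33-fold higher (2.41 ± 1.47, n = 21). TXNRD1, a thioredoxin reductase, was 3.91-fold higher (1.97 ± 1.10) and the mitotic kinase CDK1 3.60-fold higher (1.85 ± 0.71), both above 0 in 21 of 21 cases. KPNA2, a nuclear import adaptor, stood at 1.74 ± 0.63, the cohesin subunit RAD21 at 1.48 ± 0.61 and SQLE, an enzyme of cholesterol synthesis, at 1.55 ± 0.84, again above 0 in 21 of 21 cases. ANXA2, SNRPE, EIF3H, PCLAF and NME2 completed the 12 genes with the highest ratios, at 1.78, 1.58, 1.52, 1.52 and 1.47. At the other end, CYP2E1, a cytochrome P450 of ethanol metabolism, stood at -3.44 ± 1.85 (n = 21), 10.9-fold lower in tumour, and was below 0 in 20 of 21 cases. The alcohol dehydrogenases ADH4, ADH1C and ADH1B stood at -2.83, -2.63 and -2.34. TDO2 and HPD, which break down tryptophan and tyrosine, stood at -2.76 and -2.44, the metallothionein MT1X at -2.62, and the haem carrier HPX at -2.32. CYP2C8, C6, KLF9 and SAA4 stood at -2.12, -2.07, -2.06 and -2.06. The largest adjusted p among these 24 genes was 7.5e-05 (limma against 0, Benjamini-Hochberg adjustment), for SAA4. Of 8521 features tested in P, 2161 were higher and 1980 lower in tumour at an adjusted p under 0.05. Dye bias could not be separated from these ratios, because no dye swap is recorded in the labels, and the spread of the liver RNA itself is left out of the test.

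Of 36 gene groups fixed in advance, 21 passed in P with a preset correlation and 1 with an estimated one. Others went both ways, such as extracellular matrix proteins (8 higher, 7 lower) and matrix proteases (5 higher, 7 lower). Of 36 cell cycle genes, a group used to fix the sign, 22 rose and 2 fell (median 0.33). FOXM1, a transcription factor of mitotic genes, stood at 0.94, the spindle checkpoint gene MAD2L1 at 1.18 and CKS2 at 1.31. The group stood apart from all other genes at an adjusted p of 1.6e-06 with a preset correlation (cameraPR), and at an adjusted p = 0.11 with an estimated correlation. Proteasome subunits rose in 12 of 15 genes, among them PSMD11 (0.80) and PSMD1 (0.84), while 1 fell. Theirs was the only group call in P that held with an estimated correlation (adjusted p = 0.031, and 1.6e-06 with the preset one). Ribosomal proteins rose in 12 of 14 genes, with RPLP1 at 1.32 (adjusted p = 1.6e-06, and adjusted p = 0.12 with an estimated correlation). Splicing factors rose in 16 of 20 genes, with SNRPD3 at 0.69 (adjusted p = 1.6e-06, and adjusted p = 0.099 with an estimated correlation). Oncofetal and carcinoma markers rose in 9 of 13 genes, among them ROBO1 at 0.98 and the chaperone HSP90AB1 at 1.21 (adjusted p = 0.00014, and adjusted p = 0.10 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 13, including FDPS (1.39), SREBF2 (0.57) and IDI1 (1.05), and fell in 1 (adjusted p = 0.00055, and adjusted p = 0.10 with an estimated correlation). Adjusted over the list alone, the counts were 22 higher for the cell cycle, 13 for the proteasome and 16 for splicing.

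Hepatocyte functions made up most of the lower groups. Complement and coagulation genes fell in 21 of 24 and rose in 0, with a median of -0.99. Examples were C1R at -1.73, C8A at -1.86 and F11, a clotting factor, at -1.16 (adjusted p = 1.2e-08, and adjusted p = 0.12 with an estimated correlation). Urea cycle and amino acid catabolism genes fell in 20 of 26, including GLYAT (-1.83) and AGXT (-1.30), and rose in 2 (adjusted p = 1.6e-06, and adjusted p = 0.19 with an estimated correlation). Cytochromes P450 and phase II enzymes, also used to fix the sign, fell in 15 of 22, including NAT2 at -1.78 and CYP27A1 at -0.77, and rose in 1 (adjusted p = 5.7e-05, and adjusted p = 0.12 with an estimated correlation). Acute phase proteins fell in 9 of 10, with A2M at -1.63 and HP at -2.01 (adjusted p = 5.7e-05, and adjusted p = 0.12 with an estimated correlation). Fatty acid oxidation genes fell in 11 of 17, with ACAA1 at -1.07 and EHHADH at -0.70, and rose in 1 (adjusted p = 0.00045, and adjusted p = 0.22 with an estimated correlation). APOA1, the main protein of high density lipoprotein, stood at -2.04 and the vitamin E carrier AFM at -1.70. ALB stood only at -0.47 ± 0.83, yet lay below 0 in 21 of 21 P cases. Markers of Kupffer cells and macrophages fell in 9 of 11 genes, with CD5L at -1.36, CD163 at -0.68 and MARCO at -0.56 (adjusted p = 0.0013, and adjusted p = 0.23 with an estimated correlation). T and natural killer cell markers fell in 5 of 18, including NKG7 (-0.47) and CD2 (-0.58), at an adjusted p = 0.043, and adjusted p = 0.36 with an estimated correlation. That share of calls is near the share of all features (1980 of 8521 lower), while 16 of the 18 markers had a mean below 0. Markers of endothelial cells, bile duct cells, stellate cells, B cells, neutrophils and red blood cells passed in neither form of the test in P.

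The 24 genes named for P also passed in M, whose cases are all P cases, and in PN. Of all features tested, 48.6% passed in M and 38.4% in PN. The limit on dye bias given above holds for these groups too. GPC3 stood at 2.63 ± 1.78 (n = 20) in M and 2.45 ± 2.07 (n = 12) in PN, and CYP2E1 at -3.44 ± 1.80 and -2.77 ± 2.52. CDK1 stood at 1.97 ± 0.81 in M and 1.57 ± 0.90 in PN. ALB lay below 0 in 20 of 20 M cases, at -0.64 ± 1.53 (adjusted p = 0.092), and in 12 of 12 PN cases, at -1.32 ± 1.48 (adjusted p = 0.012). RHOC, a small GTPase, stood at 0.29 ± 0.52 in P (adjusted p = 0.029), 0.19 ± 0.40 in M (adjusted p = 0.072) and 0.16 ± 0.56 in PN (adjusted p = 0.42). MMP9, a matrix protease, had enough values only in PN, where it stood at -0.78 ± 0.45 in 10 cases (adjusted p = 0.00084). SPP1 and AFP were not analysed here. In M, 2182 features were higher and 1951 lower of 8509 tested, and in PN 1648 and 1626 of 8518. With the preset correlation 21 of 36 lists passed in P, 20 in M and 17 in PN, and with an estimated correlation 1, 4 and 0. The 4 in M were ribosomal proteins (adjusted p = 0.049), splicing factors (0.026), proteasome subunits (0.031) and translation factors (0.026). In PN the cell cycle list did not pass (cameraPR, adjusted p = 0.072 with the preset correlation). There 11 of its 36 genes were called higher and 3 lower, at a median of 0.012.

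**Figure D1:**
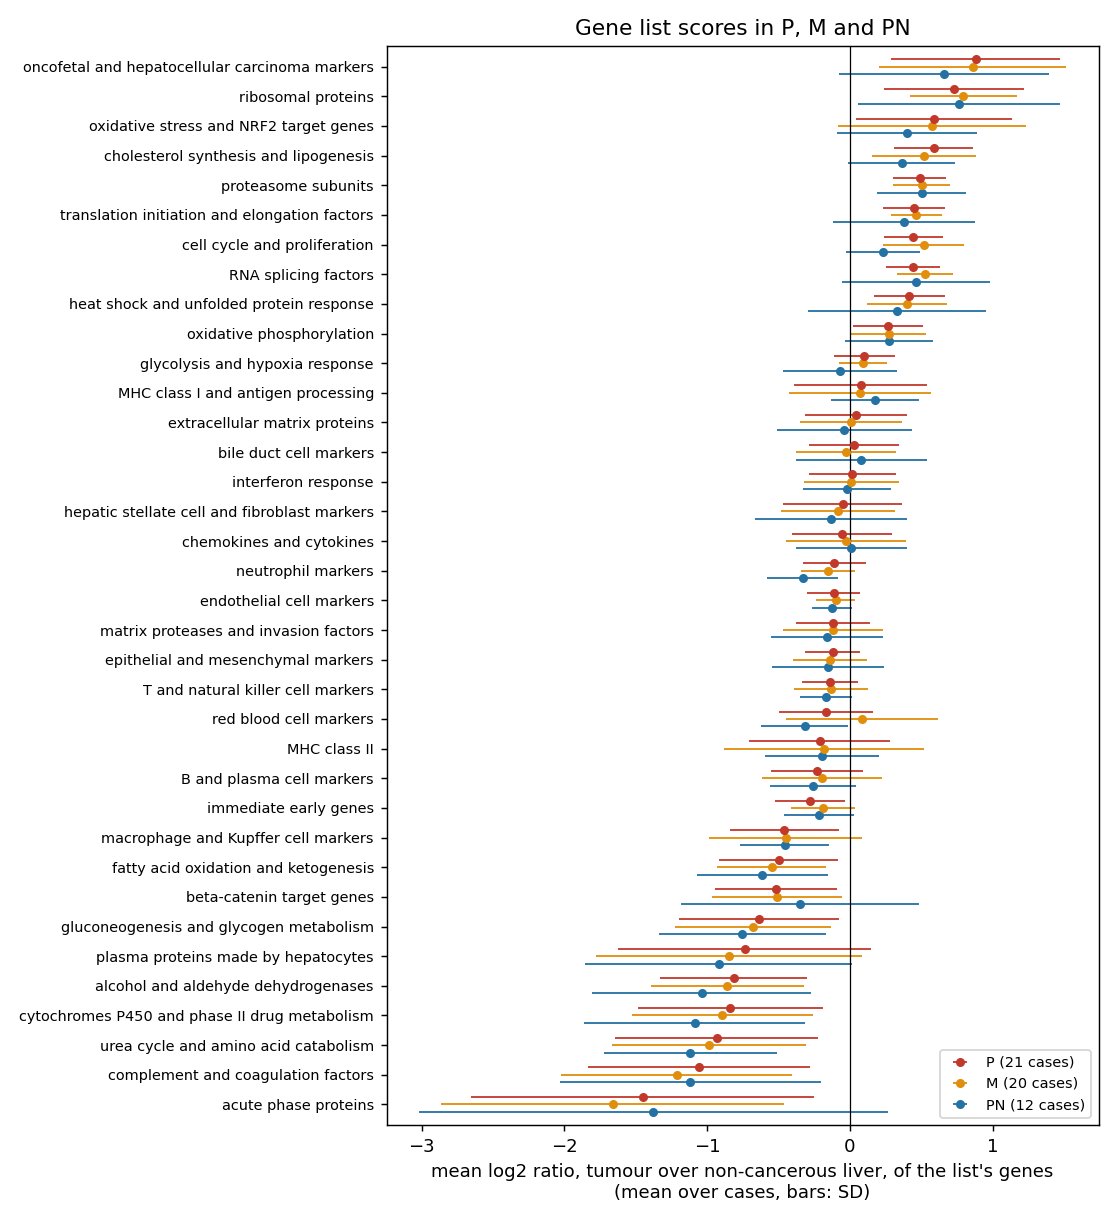
The x axis gives the mean log2 ratio of tumour over non-cancerous liver over the genes of each list on the y axis; points are means over cases of P, M and PN and bars are SDs. Acute phase proteins have the lowest P mean (-1.45) and oncofetal and carcinoma markers the highest (0.88).

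P and PN come from different cases, and what is known of the study, not the labels, gives the question as whether tumours with spread inside the liver differ from those without. Of the 36 cell cycle genes 32 had a higher mean in P than in PN, with a median difference of 0.25. CENPE, a mitotic kinesin, stood at 0.57 ± 0.44 in P (n = 21) and -0.18 ± 0.45 in PN (n = 12), and FEN1, a DNA replication nuclease, at 0.44 ± 0.30 and -0.06 ± 0.41. The differences of CDC25C and TK1 were 0.36 ± 0.11 (SE) and 0.35 ± 0.11 (SE). No single cell cycle gene passed over all features (adjusted p = 0.13 for CENPE), and 6 passed when adjusted over the list alone. The list passed with a preset correlation (adjusted p = 1.4e-07), and not with an estimated one (adjusted p = 0.49 with an estimated correlation). Averaged to 1 score per case it was 0.44 ± 0.21 in P and 0.23 ± 0.26 in PN, a difference of 0.21 (permutation test, two-sided, p = 0.014, adjusted p = 0.25 over 36 lists). The neutrophil marker score differed by as much, at -0.11 ± 0.22 in P and -0.33 ± 0.25 in PN, a difference of 0.22 (permutation test, two-sided, p = 0.011, adjusted p = 0.25). As a list, neutrophil markers did not pass (adjusted p = 0.15). Glycolysis and hypoxia genes passed only with the preset correlation (median difference 0.17, adjusted p = 0.042, and adjusted p = 0.87 with an estimated correlation), and that call was lost in 14 of 33 fits that left out 1 case (lowest mean difference 0.09, against 0.17 with all cases). Among them ENO2 differed by 0.76 ± 0.20 (SE), PDK1 by 0.39 ± 0.13 (SE) and PGAM1 by 0.57 ± 0.21 (SE). GPC3 differed by 0.33 ± 0.60 (SE, adjusted p = 0.87), RHOC by 0.13 ± 0.19 (SE, adjusted p = 0.83) and ALB by 0.85 ± 0.38 (SE, adjusted p = 0.42).

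Over all features, limma called 0 of 8478 between P and PN at an adjusted p under 0.05, and the smallest adjusted p was 0.094. At an unadjusted p under 0.05 there were 892 features, against 423.9 by chance. The array numbers in the submitters' database do not overlap between P and PN, so array order and group cannot be told apart. With that number as a covariate the cell cycle score differed by 0.35 (95% interval 0.073 to 0.62).

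M samples were also set against PN, which shares its 12 PN cases with the comparison above. Every M case also had a P sample, so the result is not independent of that comparison. The cell cycle list again had 32 of 36 genes higher, with a median difference of 0.28 (adjusted p = 1.7e-10, and adjusted p = 0.27 with an estimated correlation), and 8 genes passed adjusted over the list alone. The cell cycle score per case differed by 0.29 (permutation test, two-sided, p = 0.0064, adjusted p = 0.23), the red blood cell score by 0.40 (p = 0.023, adjusted p = 0.34) and the neutrophil marker score by 0.18 (p = 0.028, adjusted p = 0.34). CENPE differed by 0.81 ± 0.20 (SE), HMMR, a spindle protein, by 0.45 ± 0.13 (SE) and CDC25C by 0.42 ± 0.12 (SE). The 4 red blood cell genes were all higher in M, with a median difference of 0.42 (adjusted p = 0.0095, and adjusted p = 0.27 with an estimated correlation). Of these EPB42 differed by 0.38 ± 0.09 (SE) and HBD by 0.51 ± 0.26 (SE). Glycolysis and hypoxia genes were higher by a median of 0.17 (adjusted p = 0.021, and adjusted p = 0.37 with an estimated correlation). That call was lost in 4 of 32 fits that left out 1 case (highest adjusted p 0.16, lowest mean difference 0.08, against 0.16 with all cases). GPC3, RHOC and ALB differed by 0.18, 0.03 and 0.68, none past the threshold. Over all features limma called 0 of 8457, with 853 at an unadjusted p under 0.05 against 422.9 by chance. MDFI, an inhibitor of myogenic transcription factors that was chosen after its values were seen, had the smallest p, at -0.43 ± 0.29 in M (n = 18) and -1.04 ± 0.28 in PN (n = 11, adjusted p = 0.065). It passed in the fit with array weights (adjusted p = 0.033). The database numbers of M and PN do not overlap either, so array order and group cannot be told apart here.

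The differences of P from PN and of M from PN correlated at r = 0.89 over 8437 features, which are not independent replicates. Unchanged groups simulated with the same shared cases gave 0.87. The covariance was 0.039, against 0.025 in the simulation. With the PN cases split into separate sets of 6 the correlation was 0.30 (median of 100 draws). Unchanged groups simulated with that split, in which P and M still share cases, gave a median of 0.15 and a range of -0.59 to 0.88, a simulation added after the data were seen. The value of 0.30 lies within that range and so is no evidence of a shared difference.

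What is known of the study, not the labels, gives the question for P and M of a case as whether a tumour and its spread inside the liver differ. All 24 complement and coagulation genes had a lower mean in M, with a median difference of -0.15. The list passed without the case as a block (adjusted p = 0.0027, and adjusted p = 0.98 with an estimated correlation). With the case as a block it passed in both forms, at a median of -0.20 (adjusted p = 1.5e-13, and adjusted p = 0.042 with an estimated correlation). C1R, a protease that starts the complement cascade, differed within cases by -0.47 ± 0.08 (SE) and its partner C1S by -0.58 ± 0.11 (SE), both higher in M in only 3 of 20 cases (adjusted p = 0.064 for both), and these 2 passed adjusted over the list alone. Acute phase proteins passed with the block alone (median -0.23, adjusted p = 2.6e-06, and adjusted p = 0.042 with an estimated correlation), with FGL1 at -0.61 ± 0.22 (SE) and SAA1 at -0.34 ± 0.16 (SE). Per case, the complement score was lower in M in 16 of 20 cases, by a mean of -0.21 ± 0.33 (SD, n = 20; sign-turning permutation test, two-sided, p = 0.0062, adjusted p = 0.11 over 36 lists). The acute phase score was lower in 15 of 20 cases, by a mean of -0.28 ± 0.49 (SD, n = 20; p = 0.017, adjusted p = 0.20 in the same permutation test). Without the block the complement call was lost in 1 of 21 fits that left out 1 case (adjusted p = 0.064), and the mean difference of the list ran from -0.22 to -0.10 over these fits, against -0.16 with all cases.

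Without the block, the 4 red blood cell genes were higher in M by a median of 0.20 (adjusted p = 0.0074, and adjusted p = 0.22 with an estimated correlation). With the block 2 of them were higher and 2 lower, with a median of 0.17 (adjusted p = 0.010, and adjusted p = 0.055 with an estimated correlation). With the block the globins HBD and HBB differed by 0.60 ± 0.17 (SE) and 0.34 ± 0.10 (SE), each higher in M in 15 of 20 cases, and the red cell membrane genes SLC4A1 and EPB42 by -0.0037 and -0.0062. The red blood cell score per case was higher in M in 14 of 20 cases, by a mean of 0.23 ± 0.33 (SD, n = 20; sign-turning permutation test, two-sided, p = 0.0056, adjusted p = 0.11). In the fit without the block, splicing factors were higher in M in 19 of 20 genes, with HNRNPA1 at 0.19 ± 0.12 (SE) and HNRNPK at 0.18 ± 0.12 (SE) (adjusted p = 0.0027, and adjusted p = 0.56 with an estimated correlation). In that fit cell cycle genes were higher in 29 of 36 (median 0.09, adjusted p = 0.0074, and adjusted p = 0.98 with an estimated correlation), and immediate early genes in 10 of 11 (median 0.09, adjusted p = 0.021, and adjusted p = 0.22 with an estimated correlation). Leaving out 1 case ended the cell cycle call in 2 of 21 fits and the immediate early call in 5. Per case, the splicing, cell cycle and immediate early scores were higher in M in 12, 14 and 13 of 20 cases. Each had an adjusted p of 0.33 (sign-turning permutation test, two-sided, over 36 lists). Without the block the 5 genes with the smallest p were CES4A (0.58 ± 0.19 SE), COL8A1 (-0.25 ± 0.09 SE), UBE4B (0.23 ± 0.09 SE), HBD (0.59 ± 0.22 SE) and AKAP13 (-0.25 ± 0.10 SE), none past the threshold. With the block they were C1R, C1S, RDH16 (-0.33 ± 0.08 SE), HTRA1 (-0.35 ± 0.09 SE) and CES4A (0.54 ± 0.14 SE), also none past it; RDH16 and HTRA1 were chosen after their values were seen. Within cases, with the block, GPC3 differed by -0.12 ± 0.21 (SE), RHOC by -0.11 ± 0.10 (SE) and ALB by -0.20 ± 0.15 (SE), none past the threshold. Without the block limma called 0 of 8475 features, with 36 at an unadjusted p under 0.05, against 423.8 by chance. That fit treats P and M of a case as independent, although they correlated within cases, so its p-values are not well calibrated. The list calls without the block come from that same fit. With the block limma called 0 of 8482, with 399 at an unadjusted p under 0.05 and a smallest adjusted p of 0.064. With the block 13 lists passed at the preset correlation, 5 higher and 8 lower in M, against 5 without it, and 2 of the 13, complement and acute phase, held with an estimated correlation. The other 6 lower in M were hepatocyte plasma proteins (adjusted p = 0.00015), urea cycle and amino acid catabolism (0.00050), cytochromes P450 and phase II enzymes (0.0017), fatty acid oxidation (0.0099), gluconeogenesis (0.041) and cholesterol synthesis (0.041). Ribosomal proteins were higher in M (adjusted p = 0.00073).

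**Figure D2:**
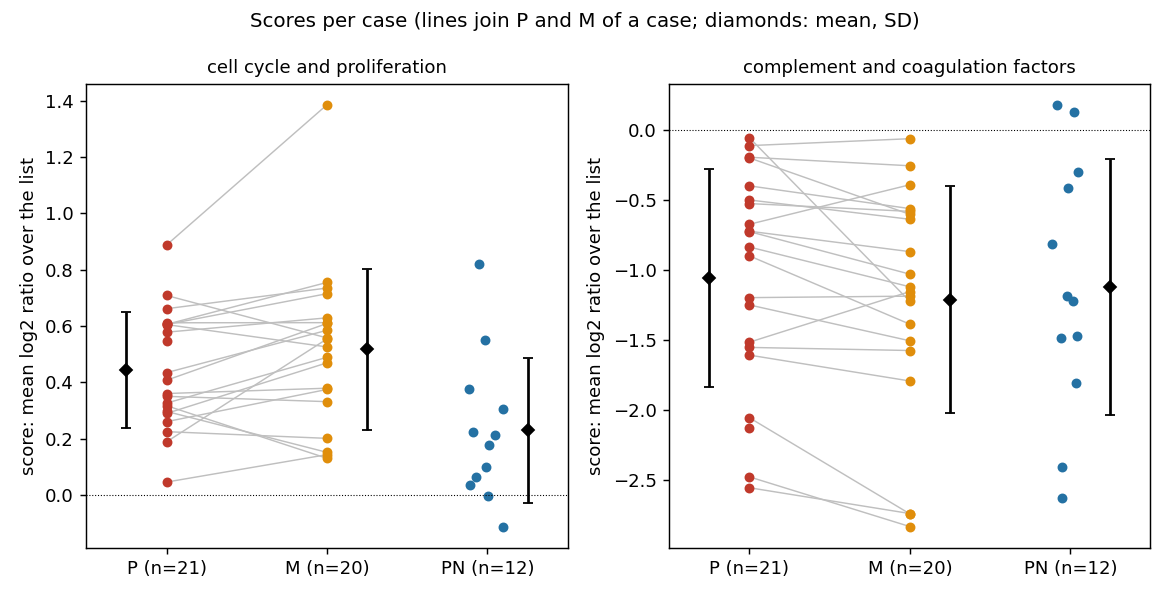
The y axes give each case's mean log2 ratio over the cell cycle list (left) and the complement and coagulation list (right) for P, M and PN; dots are cases, lines join P and M of a case, and diamonds with bars are means and SDs. Cell cycle means are 0.44 in P, 0.52 in M and 0.23 in PN, and the complement score is lower in M in 16 of 20 joined cases.

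The last comparison asked whether P and M of a case resemble each other more than those of different cases. After each feature was centred on its group mean, the correlation over 8475 features was 0.64 ± 0.13 (SD, n = 20) within a case and -0.03 between cases. Within-case values ran from 0.20 to 0.79, and the highest value between cases was 0.46. The mean within a case was tested against permuted case numbers (permutation test, one-sided, p = 1e-05, the smallest that 100000 permutations can give). In 20 of 20 cases the P sample correlated best with the M sample of its own case, and in 18 of 20 with Spearman's correlation. These counts were not tested. Whether P and M of a case were set against the same liver RNA is not stated in the labels, and a liver RNA shared within a case would by itself raise this correlation. The arrays of a case also had neighbouring database numbers. In a check chosen after the data were seen, on array 1 of each case, 36 pairs of different cases at most 4 numbers apart had a mean correlation of -0.00105, against 0.62 within a case.

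**Figure D3:**
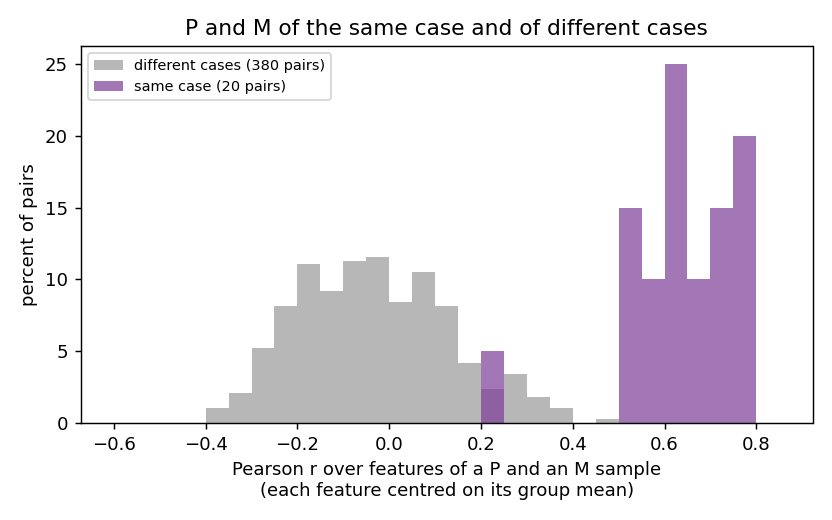
The x axis gives the Pearson correlation of a P and an M sample over features centred on their group means, and the y axis the percent of pairs; purple bars are pairs of the same case and grey bars pairs of different cases. Same-case pairs run from 0.20 to 0.79 with a mean of 0.64, and pairs of different cases have a mean of -0.03.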

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

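The counts of other sample splits, the scaling of arrays to one spread and the permutation tests of list scores were chosen only after results were seen. Differences between groups in the effect against liver, and signals in arrays outside the comparisons, are listed here.

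The cell cycle list was higher in P than in PN (median difference 0.25) and in M than in PN (0.28). With an estimated correlation the adjusted p was 0.49 and 0.27, and the per-case scores had an adjusted permutation p of 0.25 and 0.23. Array order cannot be told apart from the group, since the database numbers of PN overlap neither those of P nor those of M; the P minus PN score was 0.21 without and 0.35 with that number as a covariate. A wider spread of ratios on some arrays is argued against as the whole cause, because scaling to one spread did not shrink the difference. The score difference was 0.24 after scaling (permutation p = 0.0089, not adjusted over lists) and 0.21 before. More lymphocytes in P are likewise argued against as the whole cause, because the difference was 0.22 (95% interval 0.050 to 0.39) with both lymphocyte scores as covariates. These scores do not tell dividing lymphocytes from others and differed between P and PN by only 0.028 and 0.032. A higher dividing share among lymphocytes thus stays open. A difference between the tumours that P and PN stand for stays open and untested, and array order keeps it so.

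The complement and coagulation list was lower in M than in P (median difference -0.15; adjusted p = 0.98 with an estimated correlation, and 0.042 with the case as a block; permutation adjusted p of the scores 0.11). Scaling arrays to one spread left the mean score within cases at -0.20 (sign-turning permutation p = 0.028, not adjusted over lists), against -0.21 before. The nearly unchanged size argues against array spread as the whole cause. More non-tumour liver RNA in P may lie behind it: genes under -1 in PN shifted by -0.13 in M (95% interval -0.27 to -0.02) and genes above 1 by 0.05 (-0.04 to 0.15). The ratio of these outward shifts was 2.56, with a 95% bootstrap interval from 0.33 without an upper bound, so this explanation and a lower expression in M tumour cells cannot be told apart.

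Glycolysis and hypoxia genes differed by a median of 0.17 between P and PN and 0.17 between M and PN. Red blood cell genes differed by 0.42 between M and PN and 0.20 between M and P. Between M and P the cell cycle list differed by 0.0852, immediate early genes by 0.0856 and splicing factors by 0.076, and none of these calls held with an estimated correlation. On the T array, which no comparison used, the cell cycle score was 0.66 above liver, against 0.55 for the P sample of that case. On the 7 arrays without a group the median cell cycle score was 0.78, with a range of 0.14 to 1.08.

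Of 100 splits of the cases of P and PN, 7 gave as many as the 892 features at an unadjusted p under 0.05 (highest other 1572), so chance is not excluded. For M against PN 4 of 100 splits reached 853 (highest other 1028), a share just under 0.05. With 100 splits, counts of 4 and 7 are too close to tell apart, so chance is not excluded here either. Array order stays open as well. For M against P all 100 splits reached 36, with a highest other of 1329, several times the real count; this points to the structure of the samples, since the real split parts all 20 pairs of a case and the others keep some pairs together. Among draws that part every pair, made by turning the sign of pairs at random, 33 of 100 draws reached 399 (highest other 708).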

How the results depend on the processing

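Scaling to one median absolute deviation, leaving out arrays with fewer than 8500 probes and the permutation test of list scores were chosen after the data were seen. Counts against liver ranged from 3621 to 4627 in P, 3508 to 4357 in M and 3068 to 3821 in PN over 11 alternatives, and at an unadjusted p under 0.001 were 2523, 2529 and 1504. That limit, looser than the adjusted one where 0 features passed, gave 28 features for P against PN and 30 for M against PN. For M against PN, where the count was 0, 2 features passed with all arrays and a random block, 6 with array weights and 5 without the low-probe arrays; MDFI, named after its values were seen, was among them each time. Leaving out 1 case gave 0 to 4 features for M against PN, 0 to 4 for P against PN and 0 for M against P. MDFI passed in all 6 of the M against PN fits that gave any, and CENPE in 2 of the 4 for P against PN. With an estimated correlation the lists past the threshold fell from 21 to 1 in P, from 20 to 4 in M, from 17 to 0 in PN, from 2 to 0 for P against PN, from 3 to 0 for M against PN and from 5 to 0 for M against P. The permutation test of list scores gave 0 lists in each of the 3 comparisons between groups. For P against PN, lists past the threshold numbered 4 with scaling to one median absolute deviation, 1 without the low-probe arrays, 1 with only the array numbered 1 and 5 with the database number as a covariate. For M against PN they numbered 5 with that scaling. For M against P they numbered 3 with only the array numbered 1, 9 with only cases that have both samples and 13 with the case as a replicate block, which left the count of features past the threshold at 0. Leaving out 1 case gave 1 to 5 lists for P against PN, 2 to 4 for M against PN and 3 to 9 for M against P. The cell cycle call of P against PN and of M against PN was lost in 0 such fits, the glycolysis call in 14 of 33 and 4 of 32. For M against P the cell cycle call was lost in 2 of 21 (highest adjusted p 0.19), immediate early genes in 5 and complement in 1 (adjusted p 0.064). The cause was not tested for any of these, except that the unadjusted limit and the estimated correlation act by their construction. Within-case correlation stayed above that between cases with Spearman's method (0.57, best within the own case in 18 of 20) and with array 1 only (0.61). For named genes, 4050 of 4109 values kept sign and side of the threshold, 17 lost and 31 gained a call, 11 uncalled ones changed sign and 0 called ones did. Most of these genes were chosen by their ratios or p-values in these data. The 914 values between groups belong to genes not called in the main fit. That share thus does not measure robustness. Signal over background was not used here, so what dim spots limit is unknown.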

Other observations

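All tests in this part, of list scores and of neighbouring genes, were chosen only after the data were seen.

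Across the 21 P cases, a higher cell cycle score went with lower scores of several liver lists and of some immune lists. The lists named below had a mean score below 0 in P, against 0.44 for the cell cycle. Array spread (SD of log2 ratios 0.44 to 0.91 on P arrays) or non-tumour liver RNA could by itself move such scores apart. Neither was tested for these relations. The cell cycle score correlated with the complement and coagulation score at Pearson's r = -0.70 (permutation p = 0.00053, adjusted p = 0.011 over 35 relations) and Spearman's rho = -0.62 (p = 0.0036, adjusted p = 0.031). Without the 2 cases farthest from the median cell cycle score r was -0.57, and given the database number -0.67. For Kupffer cell and macrophage markers r was -0.66 and rho -0.67 (p = 0.00098 and 0.0014, adjusted p = 0.011 and 0.031; r = -0.56 without those 2 cases). For MHC class II genes r was -0.53 and rho -0.64 (p = 0.013 and 0.0024, adjusted p = 0.041 and 0.031; r = -0.54 without those 2 cases). Endothelial cell markers gave r = -0.53 and rho = -0.58 (p = 0.014 and 0.0064, adjusted p = 0.041 and 0.045; r = -0.55 without those 2 cases) and acute phase proteins r = -0.68 and rho = -0.62 (p = 0.00075 and 0.0030, adjusted p = 0.011 and 0.031; r = -0.53 without those 2 cases). T and natural killer cell markers (r = -0.26, adjusted p = 0.41) and B and plasma cell markers (r = -0.44, adjusted p = 0.11) did not pass. In all, 12 of the 35 relations passed by Pearson's r in P, and 5 by Spearman's rho, namely those given with a rho here. In the 12 PN cases 0 passed by either. There r was 0.05 for complement, 0.02 for macrophage markers, 0.06 for MHC class II, -0.12 for acute phase proteins and -0.70 for endothelial cell markers (p = 0.011, adjusted p = 0.31); the difference between P and PN was not tested.

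Genes that neighbour each other on chromosome 8 stood high in P. In the highest of 220 windows of 25 neighbouring genes, which runs from LAPTM4B to EXT1, the median was 0.34 in P, 0.32 in M and 0.34 in PN, and 15 of 25 genes were higher and 3 lower in tumour in P. Besides EIF3H and RAD21 it held EIF3E (1.45), LAPTM4B (0.88) and PABPC1 (0.74), a poly(A)-binding protein, the last pair chosen after their values were seen. Chance placement is argued against, because the highest window reached that median in 0.2% of 1000 shuffles of gene positions. The window's probe numbers were not unusually close, since 0.591 of random gene sets had probe numbers as close together. Whether probe numbers follow the print order is not known here, so a print effect stays open. A gain of this region in some tumours is a candidate explanation: the window's genes correlated pairwise at a mean of 0.105 across PN cases, above the median of 0.035 for matched random sets, but 0.074 of those sets were as high, so the test does not decide. On chromosome 8 the adjoining window TPD52 to MTDH ranked 2 of 220, at 0.21 in P, 0.10 in M and 0.12 in PN. On the other side, SAMD12 to TG ranked 14, at 0.15, 0.18 and 0.08. The next windows outward stood at 0.07 and 0.04 in P. These neighbouring windows were not tested. The lowest window lay on chromosome 13, from SPART to KPNA3, at -0.27 in P, -0.30 in M and -0.18 in PN.

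The T array correlated with the P sample of its case at r = 0.71 over 8418 features after both were set against the P mean; whether they share a liver RNA is not stated. On it the complement score was -2.53, against -2.13 in that P sample, and the acute phase score was -3.29, against -2.91. Over the 7 arrays without a group the complement score had a median of -1.91 (range -2.77 to 0.54) and the cytochrome P450 score a median of -1.32 (range -2.77 to -0.15).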
